A study of Mus musculus with 6 samples.

How the data were processed

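RNA was measured in bone marrow-derived macrophages on Affymetrix expression arrays, with 1 array for each of 6 samples. Per the labels, 3 samples came from wild-type mice (WT) and 3 from mice with a Gps2 knockout (GPS2KO). The labels give the knockout only as KO or MKO, without the deleted exons or a Cre driver. All mice were male and 12 to 16 weeks old. The marrow cells were differentiated for 7 days in medium conditioned by L929 cells, and received no stimulus. L929 is a fibroblast line whose supernatant supplies macrophage growth factor. Groups and replicate numbers were taken from the sample titles.

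The deposited values were log2 intensities, 1 per probe set and array. Per the submitters' processing notes, the authors made them with RMA in the R package oligo. RMA corrects background, applies quantile normalization across arrays and summarises the probes of a probe set by median polish. The versions and the array annotation package were not given in the sources used here. The log2 scale was read from the values: they ran from 2.42 to 14.0, and the array medians lay between 5.57 and 5.60. Median polish and normalization across all 6 arrays make arrays more alike, so a change shared by most genes would not be seen. The values carried no detection calls. Background left in dim signals compresses their fold changes.

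The table held 35556 probe sets. GEO's platform annotation, which can be old, listed 23099 of them. Exactly 1 gene symbol was given for 21218 probe sets and several for 1881, while 12457 were not listed and are unnamed here. Of the probe sets with 1 symbol, 21185 matched the RefSeq annotation of assembly GRCm38.p6 by gene number, 33 did not match, and 0 symbols changed. Where a gene had several probe sets, which was so for 1386 genes, the one with the highest mean over all 6 arrays stood for it. This left 18820 tested genes. The build used for the array was not given in the sources used here, so the annotation served only for names and for the order of neighbouring genes.

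Each gene was tested with limma 3.58.1 in R 4.3.3, by lmFit and eBayes on the deposited values with group as the only term. The p-values were 2-sided and were adjusted over all tested genes by the Benjamini-Hochberg method, with a threshold of 0.05. Changes are GPS2KO minus WT on the log2 scale, with limma's standard error (SE). Gps2 also had an exact permutation test of the group means. Arrays have no read depth, and their number limits the precision. No filter on dim genes was applied. A gene was called dim where its mean over the arrays lay under 5.49, the 40th percentile of the tested genes.

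The groups, the tests, the threshold, 24 gene lists, the rule for naming genes and the alternative settings were fixed before the data were examined. The lists covered the GPS2 co-repressor complex, pathways of resting and activated macrophages, and markers of other cell types that marrow cultures can hold. They held 555 symbols, of which 3 were updated to current ones. A total of 490 distinct genes was tested and 53 members were not analysed here. List shifts were tested with camera at a preset correlation of 0.01, adjusted over the 24 lists by Benjamini-Hochberg. Camera with an estimated correlation and fry were alternatives. For the genes around Gps2, camera was adjusted over the 3 neighbourhood sizes tried, a step chosen after the data were seen. Each list was also tested without its member of largest change, likewise chosen after the data were seen. The rule named every measured member of the GPS2 complex, the 10 largest rises and 10 largest falls among genes past the threshold whose groups did not overlap, up to 4 members of each list by smallest p, and Lyz2. Predicted or unnamed gene models and small RNAs were passed over, which concerned 41 genes past the threshold. Further members were named, after their values were seen, where a count was 5 or fewer or where neighbouring genes and families are described. These were Il10, Cxcl2, Ccl5, Tlr2, Tlr4, Tlr7, Tlr9, Tlr13, Tnfaip3, Cd5l, Stab1, Pfkfb3, Cd86, Itgam, Dcn, Fgf11, Dlg4, S100a8, S100a9 and the genes given by name only under other observations. Of the genes named by the rule, Bnip3, Fabp5, Ndufs3, Phgdh, Tbl1xr1 and Tk1 had several probe sets, and those of each gene changed in 1 direction. The genes named after their values were seen were not checked in this way.

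The calculation was tested on simulated data with the means and spreads of the 18820 genes. For GPS2KO against WT, limma called 85% of 100 genes planted with a log2 change of 0.5, 98% of 50 planted with 1 and 100% of 50 planted with 2. It also called 10 unchanged genes. A list shifted by 0.2 had an adjusted p of 1.11e-29 in camera, and 0 other lists were called. The simulated genes were drawn independently of each other. The simulation therefore does not test list calls where genes of a list move together.

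The alternatives were quantile normalization of the deposited values, centring each array on its median, limma with a variance trend, with and without robust estimation, array quality weights, leaving out dim genes, averaging the probe sets of a gene, the replicate number as a block, leaving out each array in turn, testing all probe sets, a threshold of 0.1, an ordinary t statistic, and other sizes of the neighbourhood around Gps2. The labels give no batch, slide or scan date, and none was tested.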

Results

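Gene expression was compared between bone marrow-derived macrophages of WT and GPS2KO mice, cultured without a stimulus. GPS2, G protein pathway suppressor 2, is a subunit of a nuclear co-repressor complex that also holds the deacetylase HDAC3 and TBL1. The comparison asks which genes differ in resting macrophages when GPS2 is lost. Each group had 3 arrays, and the number of arrays limits the precision. Array medians ran from 5.57 to 5.60 on the log2 scale. Pearson correlations across genes ran from 0.9989 to 0.9991 within groups and from 0.9977 to 0.9981 between groups, and the first principal component, with 52.4% of the variance, separated the groups. The labels do not tie each array to a separate animal, so p-values measure only the spread between these samples, which may be technical.

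Gps2 itself was examined first, as a check of the labels. Its log2 signal was 10.943, 10.931 and 11.002 on the WT arrays and 10.289, 10.164 and 10.187 on the GPS2KO arrays. The means were 10.96 ± 0.04 and 10.21 ± 0.07 (SD, n = 3 each). Gps2 fell by 0.75 (SE 0.0472, 95% confidence interval -0.86 to -0.64; adjusted p = 0.000256, limma with Benjamini-Hochberg), to 59.7% of the WT signal. The groups did not overlap, and an exact 2-sided permutation test gave p = 0.1, the smallest that the 20 arrangements of 6 arrays allow. The labels do not state which exons were deleted, and probes outside the deleted part would check nothing. Among the other 6 measured members of the complex 0 passed the threshold. Coro2a differed by -0.18 (adjusted p = 0.0713) but passed after median centring, with a variance trend and without dim genes, at adjusted p as low as 0.00783. Hdac3 differed by -0.08 (adjusted p = 0.298), and Tbl1x, Tbl1xr1, Kdm4a and Zbtb33 lay between -0.07 and 0.07. Adjusted over the list alone, 0 members rose and 2 fell, Gps2 and Coro2a. The list, which includes Gps2, did not pass (camera adjusted p = 0.073), though it did without GPS2KO replicate 2 (adjusted p = 0.0461) and with a variance trend (adjusted p = 0.0249). Without Gps2 the other 6 members had adjusted p = 0.403.

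**Figure D1:**
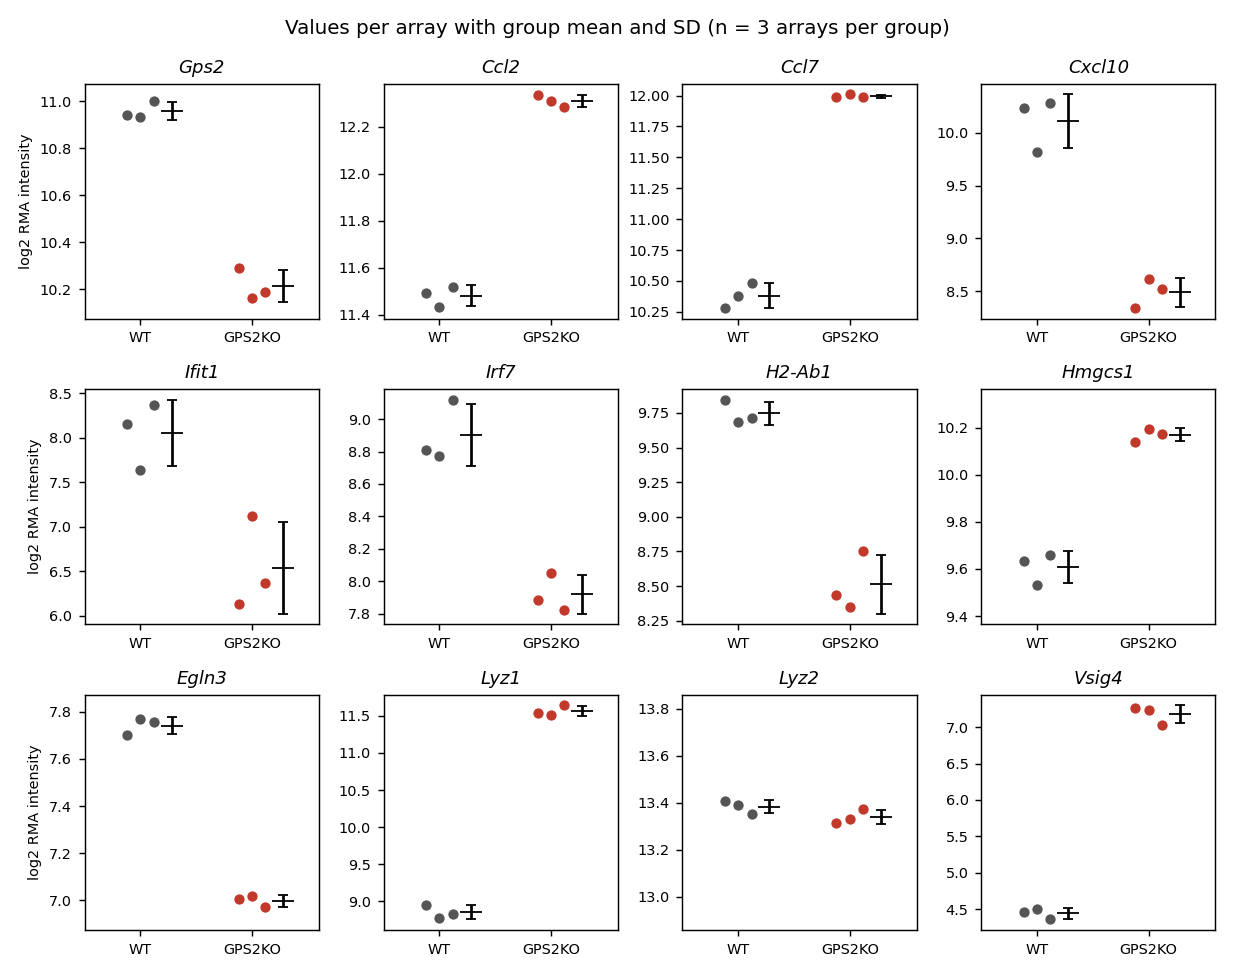
Log2 RMA intensity of 12 genes on each array, with points for the arrays and bars for the group mean and SD (n = 3 per group); the y axes cover different ranges. The Gps2 points of the GPS2KO group reach at most 10.29, under the lowest WT value of 10.93, while the Lyz2 groups, at means of 13.38 and 13.34, overlap.

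In unstimulated GPS2KO macrophages, 25 of 33 interferon-stimulated genes and 9 of 19 genes of antigen presentation fell, while 9 of 20 genes of cholesterol synthesis and uptake rose. These lists passed camera at its preset correlation, but with an estimated correlation they had adjusted p = 0.141, 0.0988 and 0.0988. The largest rises were those of Lyz1, which encodes a lysozyme, by 2.71 on the log2 scale (SE 0.059, 6.56-fold), and of Vsig4, a complement receptor of tissue macrophages, by 2.73 (SE 0.0694, 6.65-fold). The WT mean of Vsig4, 4.44, lay among the dim signals, under 5.49, where background compresses fold changes, so its fold has no firm upper bound and the order of these 2 rises is not settled. Ccl7, a chemokine for monocytes, rose by 1.61 (SE 0.0546, 3.06-fold). Cxcl10, an interferon-induced chemokine for T cells, fell by 1.62 (SE 0.126, 3.07-fold), and Ifit3, an antiviral protein, fell by 1.52 (SE 0.217, 2.86-fold), each with n = 3 per group. The limma adjusted p-values were 4.47e-06 for Vsig4, 2.81e-06 for Lyz1, 1.96e-05 for Ccl7, 0.000479 for Cxcl10 and 0.00664 for Ifit3.

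Beyond these, the 10 largest rises held Mamdc2 (1.597 on the log2 scale), the chemokine Ccl6 (1.44), the tumour necrosis factor receptor family member Tnfrsf26 (1.39), the membrane glycoprotein podoplanin (Pdpn, 1.32), the opioid precursor proenkephalin (Penk, 1.29), the orphan receptor Mrgpre (1.28) and the lipid carrier Fabp4 (1.17). The 10 largest falls also held Ifit1 (-1.51), the chemokine Cxcl9 (-1.37), the glycolipid synthase Gbgt1 (-1.27), H2-Ab1 (-1.23), Acod1 (-1.20), which makes itaconate, H2-Aa (-1.09), Usp18 (-1.08), a protease that removes ISG15, and the protease inhibitor Serpinb6b (-1.08). The GPS2KO mean of Cxcl9, 4.84, lay under the dim limit of 5.49, so its fall, too, has no firm size or rank. Adjusted p-values of these genes ran from 1.68e-05 for Ccl6 to 0.0161 for Ifit1. The call of Ifit1 ended without WT replicate 1, WT replicate 3 or GPS2KO replicate 3, at adjusted p = 0.0618, 0.0646 and 0.0604. Tnfrsf26 and Mrgpre lie in a run of neighbouring genes of which 6 in a window of 11 rose. Among the falls, H2-Ab1 and H2-Aa lie in a run of 7 falls in such a window. Ifit3 and Ifit1 lie in another run of 7, and Gbgt1 in a run of 6.

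Of 18820 tested genes, 1265 (6.72%) passed the threshold, 545 of which rose and 720 fell. Most changes were small: the median fold was 1.23, with 66 rises and 76 falls of at least 1.5-fold and 20 rises and 15 falls of at least 2-fold. At an unadjusted p under 0.05 there were 3906 genes, against 941 expected by chance. The WT and GPS2KO arrays did not overlap for 27.1% of the tested genes, where chance gives 10%. Centring each array on its median gave 460 rises and 1061 falls, a share of rises of 30.2% against 43.1%. Leaving out any 1 of the 6 arrays left between 749 and 842 genes, each more than 1.5 times fewer. Of the 120 genes named here other than Gps2 that passed, 34 lost their call with at least 1 array left out, and these arrays are given with each gene group.

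**Figure D2:**
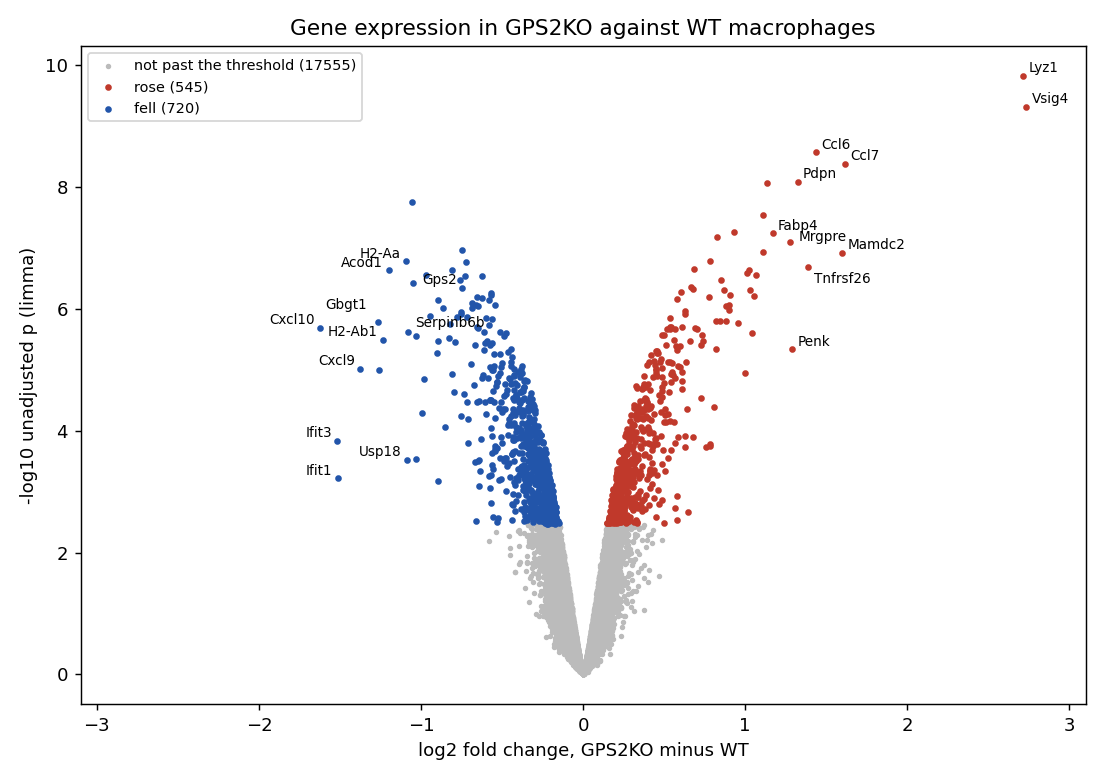
Each point is 1 of 18820 tested genes, with the log2 fold change (GPS2KO minus WT) on the x axis and the -log10 of limma's unadjusted p on the y axis; red genes rose and blue genes fell at adjusted p under 0.05. Lyz1 and Vsig4, at 2.71 and 2.73, stand apart on the right, and Cxcl10, Ifit3 and Ifit1 lie farthest to the left.

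All 33 tested interferon-stimulated genes had lower means in GPS2KO. Of these, 25 fell, 0 rose and 8 did not pass; adjusted over the list alone, 30 fell. The median was -0.45, and the list fell as a whole (camera adjusted p = 9.88e-23). Its adjusted p = 0.141 with an estimated correlation. Irf7, the transcription factor that amplifies the type I interferon response, fell from 8.90 ± 0.19 to 7.92 ± 0.12 (1.98-fold, adjusted p = 0.00149). Zbp1, a sensor of nucleic acids, fell by 0.69 (adjusted p = 0.0011), Ifit2 by 0.99 (adjusted p = 0.00324) and Isg20, an exonuclease, by 0.45 (adjusted p = 0.00168). The fibroblast and stromal list, described with the other cell types, fell alongside at a median of -0.10.

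Of 19 genes of antigen presentation, 9 fell, 1 rose and 9 did not pass, and adjusted over the list alone 12 fell and 1 rose. The median was -0.19 (camera adjusted p = 7.48e-08; adjusted p = 0.0988 with an estimated correlation). The largest falls were those of the class II chains. These lie in 1 run of neighbouring genes, and 7 of the 9 falls of the list were within that window of 11. No explanation was tested for that run. H2-Ab1 fell from 9.75 ± 0.09 to 8.51 ± 0.21 (2.35-fold, adjusted p = 0.000631), H2-Aa 2.13-fold (adjusted p = 0.000178) and H2-Eb1 2.04-fold (adjusted p = 0.000566). The costimulatory receptor Cd40 fell by 0.46 (adjusted p = 0.00417), whereas another costimulatory molecule, Cd86, rose by 0.26 (adjusted p = 0.0452). The Cd86 call ended without any array but WT replicate 3, at adjusted p up to 0.142. Class II genes are also abundant in dendritic cells, whose markers moved both ways and did not shift as a list (adjusted p = 0.875).

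Inflammatory cytokines and chemokines split. Of 27, 7 rose, 5 fell and 15 did not pass; adjusted over the list alone, 9 rose and 5 fell. The rises included the monocyte chemoattractants Ccl7 and Ccl2 and the chemokine Ccl4: Ccl2 rose from 11.48 ± 0.04 to 12.31 ± 0.02 (1.77-fold, adjusted p = 0.000112) and Ccl4 1.84-fold (adjusted p = 0.000434). The falls were Cxcl10, Cxcl9, Ccl5 (-0.56, adjusted p = 0.0088), Cxcl2 (-0.51, adjusted p = 0.0162) and the anti-inflammatory Il10 (-0.29, adjusted p = 0.0298). Without GPS2KO replicate 2, 4 members rose. The list median was 0.04 (camera adjusted p = 0.0455, up; adjusted p = 0.167 with an estimated correlation). That call also ended without WT replicate 1 (adjusted p = 0.0709), WT replicate 3 (0.114) or GPS2KO replicate 1 (0.0743), after quantile normalization (0.0557) and without dim genes (0.0554). The Il10 call ended without any array but WT replicate 1, and that of Cxcl2 without WT replicates 2 or 3 or GPS2KO replicates 2 or 3, at adjusted p up to 0.101 and 0.0662.

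Of 29 genes of Toll-like receptor and NF-kappaB signalling, 9 fell, 5 rose and 15 did not pass. Adjusted over the list alone, 9 fell and 6 rose. The falls included the inhibitor Nfkbie (1.65-fold, adjusted p = 0.000408), the NF-kappaB subunit Relb (1.53-fold, adjusted p = 0.000521) and Tnip1, which restrains the pathway (1.36-fold, adjusted p = 0.000771). The rises were those of Tlr8 (1.71-fold, adjusted p = 0.00028), Tlr7, Tlr4, Tlr13 and the inhibitor Tnfaip3. Among the receptors of nucleic acids in endosomes, Tlr7 rose by 0.53 (adjusted p = 0.00107) and Tlr9 fell by 0.57 (adjusted p = 0.00249). Tlr8 and Tlr7 are neighbours in a run of which 6 genes in a window of 11 rose, 4 of them not receptors. Of the receptors at the cell surface, Tlr4 rose by 0.31 (adjusted p = 0.00448) and Tlr2 fell by 0.38 (adjusted p = 0.00318). The list median was -0.06 (camera adjusted p = 0.022; adjusted p = 0.141 with an estimated correlation), and the list did not pass without WT replicate 2 (adjusted p = 0.0851), after quantile normalization (0.0515) or without dim genes (0.0554). The call of Tlr13 ended without any 1 of the arrays (adjusted p 0.0744 to 0.133), and that of Tnfaip3 without GPS2KO replicate 2 or 3 (up to 0.0622). On all arrays, the Tlr13 call also ended after median centring.

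Of 20 genes of cholesterol synthesis and uptake, 9 rose, 0 fell and 11 did not pass, and adjusted over the list alone 13 rose. The median was 0.20 (camera adjusted p = 1.07e-08; adjusted p = 0.0988 with an estimated correlation). Hmgcs1, which makes the precursor of mevalonate, rose from 9.61 ± 0.07 to 10.17 ± 0.03 (1.48-fold, adjusted p = 0.000629). The sterol demethylase Cyp51 rose 1.39-fold (adjusted p = 0.000997), Insig1, which retains the sterol regulator in the endoplasmic reticulum, 1.41-fold (adjusted p = 0.00416) and the sterol carrier Stard4 1.28-fold (adjusted p = 0.00637).

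Targets of the liver X receptor (LXR) did not shift as a list (18 tested, 2 rose, 3 fell, 13 did not pass; the same counts adjusted over the list alone; median 0.05, camera adjusted p = 0.339). The lipid transporter Abca9 rose 1.48-fold (adjusted p = 0.00145) and the phagocytic receptor Mertk 1.18-fold (adjusted p = 0.00991). Nr1h3, which encodes LXR alpha, fell 1.32-fold (adjusted p = 0.00299), Lpcat3 1.16-fold (adjusted p = 0.0275) and Cd5l by 0.44 (adjusted p = 0.0313). Of 21 targets of peroxisome proliferator-activated receptors (PPAR) and genes of fatty acid oxidation, 3 rose, 1 fell and 17 did not pass. Adjusted over the list alone, 3 rose and 2 fell. The fatty acid carriers Fabp4 and Fabp5 rose 2.25-fold and 1.45-fold (adjusted p = 0.000108 and 0.000479) and the scavenger receptor Cd36 1.18-fold (adjusted p = 0.00991), while Pparg itself fell by 0.18 (adjusted p = 0.0461). The median was 0.03 (camera adjusted p = 0.0455; adjusted p = 0.368 with an estimated correlation), and the list did not pass without WT replicate 2 (adjusted p = 0.116) or GPS2KO replicate 1 (0.0975) or without dim genes (0.0567), nor without Fabp4 (0.166). With a variance trend 5 PPAR genes rose and 2 fell, and 4 LXR targets rose. The Pparg call ended without any 1 of the arrays (adjusted p 0.0684 to 0.141), that of Lpcat3 without any but WT replicate 3 (up to 0.101), and that of Cd5l without any WT array or GPS2KO replicate 1 (up to 0.102).

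Of 22 genes of glycolysis and hypoxia, 7 fell, 1 rose and 14 did not pass, and adjusted over the list alone 9 fell and 1 rose. The median was -0.11 (camera adjusted p = 3.81e-06; adjusted p = 0.0988 with an estimated correlation). With a variance trend 11 members fell. Egln3, an oxygen sensor induced by hypoxia, fell from 7.74 ± 0.04 to 7.00 ± 0.02 (1.68-fold, adjusted p = 0.000149). Bnip3, which acts in mitophagy, fell 1.36-fold (adjusted p = 0.00116), the lactate transporter Slc16a3 1.30-fold (adjusted p = 0.00116) and the pyruvate dehydrogenase kinase Pdk1 1.29-fold (adjusted p = 0.00181). Pfkfb3, a regulator of glycolysis, rose by 0.25 (adjusted p = 0.0307), a call that ended without any array but GPS2KO replicate 3 (adjusted p up to 0.107). Of 30 genes of oxidative phosphorylation, 0 passed the limma threshold, also when adjusted over the list alone, and the median was -0.02 (camera adjusted p = 0.478). Of them, 4 fell with a variance trend, and 1 fell without dim genes. The smallest p in that list belonged to Sdhc (-0.14, adjusted p = 0.0948).

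Of 27 genes of lysosome and phagocytosis, 6 rose, 1 fell and 20 did not pass, and adjusted over the list alone 8 rose and 3 fell. With a variance trend 10 rose and 3 fell, and 3 rose without WT replicate 1 or any 1 of the GPS2KO arrays. The median was 0.06 (camera adjusted p = 0.000596; adjusted p = 0.0988 with an estimated correlation). Atp6v0d2, a subunit of the proton pump, rose 2.01-fold (adjusted p = 0.000194), and the cathepsins Ctsk and Ctsl rose 1.39-fold and 1.22-fold (adjusted p = 0.00107 and 0.0114). The phagocytic receptor Axl fell 1.24-fold (adjusted p = 0.00396). Atp6v0d2 and Ctsk are also osteoclast markers. That list had 15 tested genes, of which 2 rose and 2 fell and 11 did not pass (adjusted over the list alone, 3 rose and 2 fell; median 0.03, camera adjusted p = 0.119; with a variance trend 4 rose). Its falls were Ocstamp, needed for osteoclast fusion (1.61-fold, adjusted p = 0.000336), and Tnfrsf11a (1.14-fold, adjusted p = 0.0271), the latter call ending without any array but WT replicate 1 (up to 0.0936).

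Of 24 genes of macrophage identity, 4 rose, 2 fell and 18 did not pass, and adjusted over the list alone 7 rose and 3 fell. The median was 0.05 (camera adjusted p = 0.0172; adjusted p = 0.413 with an estimated correlation), and the list did not pass without WT replicate 3 (adjusted p = 0.0813) or GPS2KO replicate 1 (0.0581). It did not pass without Lyz1 either (adjusted p = 0.0735), and the mean of the other 23 members was -0.0043. In this list 8 rose and 3 fell with a variance trend. Lyz1 rose from 8.85 ± 0.09 to 11.57 ± 0.07. The adjacent gene Lyz2, the main lysozyme of macrophages, was at 13.38 ± 0.03 and 13.34 ± 0.03 (-0.04, adjusted p = 0.585), and 5 tested genes were brighter. Ccr2, the receptor of Ccl2 and Ccl7, fell 1.96-fold (adjusted p = 0.000194) and the fractalkine receptor Cx3cr1 1.46-fold (adjusted p = 0.000323). The myeloid factor Cebpa rose 1.31-fold (adjusted p = 0.00354), and so did Mertk and Itgam, the latter by 0.19 (adjusted p = 0.0279). The Itgam call ended without any 1 of the arrays (adjusted p 0.0557 to 0.1). Lyz1 and Lyz2 are near-identical paralogs, so their probes may share signal.

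Of 23 genes of alternative activation, 5 rose, 0 fell and 18 did not pass, and adjusted over the list alone 6 rose and 2 fell. The rises were those of the beta-glucan receptor Clec7a (1.83-fold, adjusted p = 0.000258), the transglutaminase F13a1 (1.66-fold, adjusted p = 0.000685), the mannose receptor Mrc1 (1.40-fold, adjusted p = 0.00121), Il4ra (1.16-fold, adjusted p = 0.0224) and Stab1 (0.21, adjusted p = 0.0347). The list did not shift (median -0.0048, mean 0.05, camera adjusted p = 0.372), but did without dim genes (adjusted p = 0.0356). The Il4ra call ended without any array but WT replicate 3 (up to 0.0858), and that of Stab1 without any but WT replicate 2 (up to 0.119).

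Immediate early genes (22 tested, 2 rose, 2 fell, 18 did not pass; 4 rose and 4 fell adjusted over the list alone) had a median of 0.02 (camera adjusted p = 0.524). Fos fell by 0.32 (adjusted p = 0.00771) and Klf2 by 0.32 (adjusted p = 0.0276), while Zfp36 rose by 0.23 (adjusted p = 0.0214) and Egr2 by 0.31 (adjusted p = 0.0474). The unfolded protein and amino acid response list (17 tested, 2 fell, 0 rose, 15 did not pass; 3 fell adjusted over the list alone) had a median of 0.00036 and a mean of -0.05 (camera adjusted p = 0.403), with falls of the mTORC1 inhibitor Ddit4 (-0.33, adjusted p = 0.0168) and of Herpud1 (-0.22, adjusted p = 0.0211). The oxidative stress list (17 tested, 2 fell, 0 rose, 15 did not pass; 2 fell and 1 rose adjusted over the list alone) had a median of 0.04 (camera adjusted p = 0.524), with falls of superoxide dismutase Sod2 (-0.25, adjusted p = 0.0121) and Osgin1 (-0.22, adjusted p = 0.0396). Of 28 cell cycle genes, thymidine kinase Tk1 passed the limma threshold (-0.32, adjusted p = 0.0114), 27 did not pass, and 3 fell and 1 rose adjusted over the list alone. Among cell cycle genes, 4 rose and 3 fell with a variance trend, and without dim genes 1 rose and 3 fell. The cell cycle median was 0.01 and its mean -0.0073 (camera adjusted p = 0.782, up). With a variance trend 5 immediate early genes rose and 3 fell, 4 of the unfolded protein list fell, and 3 of the oxidative stress list rose. Without any 1 of the arrays the call of Egr2 ended, and calls ended without any array but GPS2KO replicate 3 for Klf2, WT replicate 3 for Herpud1 and WT replicate 1 for Osgin1. On all arrays, the Egr2 call also ended after median centring and with array quality weights. The calls of Zfp36 ended without replicates 1 or 3 of either group, those of Ddit4 without any WT array or GPS2KO replicate 2, and that of Sod2 without GPS2KO replicate 2, with adjusted p up to 0.137 for Egr2, 0.0854 for Klf2, 0.0849 for Herpud1, 0.134 for Osgin1, 0.0784 for Zfp36, 0.066 for Ddit4 and 0.0534 for Sod2.

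**Figure D3:**
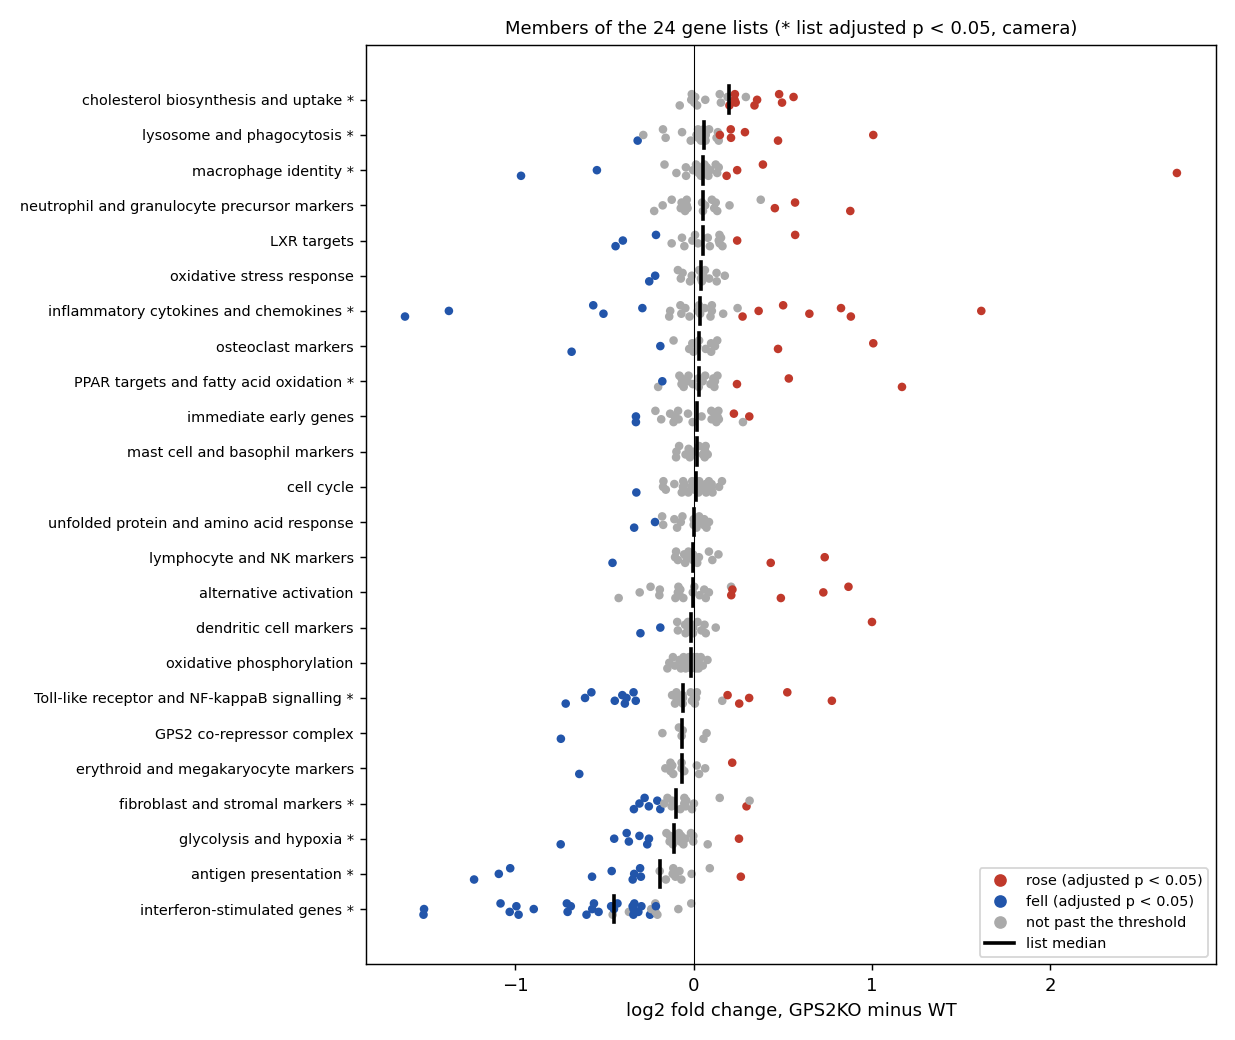
Each point is a tested member of 1 of the 24 gene lists, placed by its log2 fold change (GPS2KO minus WT); red members rose, blue members fell, grey members did not pass, and black bars mark list medians. Medians run from -0.45 for interferon-stimulated genes to 0.20 for cholesterol synthesis, and stars mark the 10 lists that passed camera.

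Among markers of other cell types, the fibroblast and stromal list fell. Of 20 tested genes, 19 of which were not dim, 6 fell, 1 rose and 13 did not pass, and adjusted over the list alone 9 fell and 1 rose. Without WT replicates 1 or 2 or GPS2KO replicates 1 or 2, 3 fell, and without WT replicate 3, 2 fell. The median was -0.10 (camera adjusted p = 0.00141; adjusted p = 0.0988 with an estimated correlation). The growth factor receptor Pdgfrb fell 1.21-fold (adjusted p = 0.00675) and the collagen chain Col6a1 1.19-fold (adjusted p = 0.00897). Thy1 fell by 0.30 (adjusted p = 0.0165) and the matrix protein Mgp by 0.34 (adjusted p = 0.0178), while the proteoglycan Dcn rose by 0.30 (adjusted p = 0.0334). The call of Thy1 ended without WT replicates 1 or 3 or GPS2KO replicate 1 (adjusted p up to 0.0562), that of Mgp without any WT array or GPS2KO replicate 2 (up to 0.0684) and that of Dcn without WT replicates 1 or 2 or GPS2KO replicates 1 or 2 (up to 0.115).

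Of 21 markers of neutrophils and their precursors, 13 of them dim, 3 rose, 0 fell and 18 did not pass, with the same counts adjusted over the list alone. The rises were those of the collagenase Mmp8 (1.84-fold, adjusted p = 0.000323), Padi4 (1.48-fold, adjusted p = 0.00701) and the granule protein Ngp (1.37-fold, adjusted p = 0.0151). The list did not pass (median 0.05, camera adjusted p = 0.0735), but it did without WT replicate 1 (0.0274), GPS2KO replicate 2 (0.0437) or GPS2KO replicate 3 (0.0386), after median centring (0.0349) and without dim genes (0.0132). The Ngp call ended without WT replicates 2 or 3 or GPS2KO replicates 1 or 2 (up to 0.0617).

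Dendritic cell markers (18 tested, 10 dim, 3 also in other lists) had 1 rise, 2 falls and 15 members that did not pass, also adjusted over the list alone, with a median of -0.02 and a mean of 0.03 (camera adjusted p = 0.875, down). Itgax, an integrin that macrophages also carry, rose to 200.2% of the WT signal (adjusted p = 0.00132), Cd24a fell 1.23-fold (adjusted p = 0.00666) and Fscn1 1.14-fold (adjusted p = 0.0264). Lymphocyte and NK cell markers (17 tested, 14 dim) had 2 rises and 1 fall, with 14 that did not pass and the same counts adjusted over the list alone, a median of -0.0043 and a mean of 0.04 (camera adjusted p = 0.524, up). The interleukin 7 receptor Il7r rose 1.67-fold (adjusted p = 0.000558) and Cd4 1.35-fold (adjusted p = 0.00142), and the B cell receptor component Cd79b fell 1.37-fold (adjusted p = 0.00373). Erythroid and megakaryocyte markers (13 tested, 9 dim) had 1 rise and 1 fall, with 11 that did not pass, also adjusted over the list alone (median -0.07, camera adjusted p = 0.331). The platelet chemokine Pf4, also bright in these macrophages at 12.17 in WT, rose by 0.22 (adjusted p = 0.0236) and Ppbp fell by 0.64 (adjusted p = 0.0196). Among 14 mast cell and basophil markers, 12 of them dim, 0 passed the limma threshold, also adjusted over the list alone (median 0.02, camera adjusted p = 0.619). The call of Fscn1 ended without any 1 of the arrays (adjusted p 0.0568 to 0.1), that of Pf4 without any but WT replicate 1 (up to 0.0816) and that of Ppbp without GPS2KO replicates 1 or 2 (up to 0.0761).

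In all, 10 of 24 lists passed camera, 5 up and 5 down. With an estimated correlation 0 passed, the smallest adjusted p being 0.0988, and 7 had an unadjusted p under 0.05. By fry, which asks whether the genes of a list move on balance in 1 direction, 13 lists passed, and by its mixed test for change in either direction 23 passed. Unlike camera, neither fry test compares a list with the other genes. The mixed test thus sets no list apart: oxidative phosphorylation, with 0 called genes, passed it too (fry mixed adjusted p = 0.00302). Median, mean and test differed in sign for 5 lists: alternative activation, cell cycle, unfolded protein response, dendritic cells and lymphocytes.

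The genes around Gps2 were examined because a knockout can carry neighbouring alleles of another strain. Among the 20 tested genes on each side in the GRCm38.p6 annotation, 0 rose and 2 fell, with a median of -0.02 (camera adjusted p = 0.269 over the 3 neighbourhood sizes tried). The falls were those of Fgf11 by 0.48 (adjusted p = 0.00991) and of the synaptic scaffold Dlg4 by 0.24 (adjusted p = 0.044), and the latter call ended without any 1 of the arrays (adjusted p 0.073 to 0.129). With 50 genes on each side, 7 of 100 fell and 1 rose, with a median of -0.03 (camera adjusted p = 0.0633 over the same 3 sizes). Without that adjustment, which was chosen after the data were seen, the 50-gene neighbourhood alone passed the threshold.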

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

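A signal outside the comparison of named genes drew attention: 153 of the 12457 probe sets that the platform annotation does not list passed the limma threshold when all 35556 probe sets were tested together. Of these, 109 rose and 44 fell in GPS2KO, and 13 changed at least 2-fold. Among the 1881 probe sets with several gene symbols, 34 passed. No explanation was tested for them.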

How the results depend on the processing

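All settings here were planned, except the adjustment over neighbourhood sizes and leaving out the largest member of each list. The latter ended the calls of the macrophage identity and PPAR lists, of 10. Gps2 stayed past the threshold in each setting run, at -0.78 to -0.72 with arrays left out. The count of 1265 genes (545 up, 720 down) moved by over 1.5 times as follows: 2174 (926, 1248) with a variance trend, 2180 (928, 1252) when that trend was robust, 2068 (851, 1217) at a threshold of 0.1, and 626 (300, 326) with an ordinary t statistic, which borrows no variance between genes. It was 1962 without dim genes (1154 down) and 824 over all probe sets (412 down). With arrays left out, it ran from 749 to 842 (322 to 376 up, 419 to 503 down), of fewer arrays, and 56.3% to 61.8% of the 1265 genes remained, in the same direction. Other settings, the replicate block aside, gave 1243 to 1521. The cause was not tested for the variance trend or the dim filter. Lists past the threshold numbered 0 with an estimated correlation and 7 to 12 with arrays left out, against 10. The median around Gps2 ran from -0.031 to -0.018 with arrays left out and, without adjustment over sizes, passed only at 50 genes on each side (-0.029; camera adjusted p = 0.0633 over 3 sizes). The interferon, cholesterol, antigen presentation, glycolysis, lysosome and fibroblast lists each kept their call in 15 of 16 settings, all but the estimated correlation. Of uncalled genes, S100a8 ran from -0.025 to 0.14 and S100a9 from -0.17 to 0.0039 with arrays left out, crossing 0 without GPS2KO replicate 1 and WT replicate 3; 0 called results changed direction. Camera with robust estimation was not run. Arrays of the same number did not deviate together (correlations 0.0035, 0.026 and -0.006), so no pairing by number was seen. Samples paired by design without such a shared deviation cannot be excluded. With the replicate block, 862 genes passed (370 up, 492 down), 9 lists passed, PPAR targets being lost, and Gps2 kept its call (-0.75, adjusted p = 0.0027). The number of arrays and signal over background limit small changes of dim genes.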

Other observations

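The tests in this part were chosen after the results were seen, except the comparison with other splits of the arrays. Called genes lay close together in several places of the genome, by their order in the GRCm38.p6 annotation. Windows of 11 neighbouring tested genes were compared with 10000 random orders of the genes, which treat genes as independent. The highest count of falls in a window was 7, reached at a run of class II and proteasome genes and at a run that holds Stambpl1, the death receptor Fas, the sterol hydroxylase Ch25h and the Ifit genes. Both had permutation p = 0.0005. Many of these are interferon-induced or paralogs, such as Ifit2, Ifit3, Ifit3b and Ifit1. Ch25h fell by 0.65 (adjusted p = 0.000323) and Fas by 0.33 (adjusted p = 0.0055). A window of 6 falls (permutation p = 0.0098) held Olfm1 (-0.57), Gbgt1 (-1.27), Ralgds (-0.54), Gtf3c5 (-0.31) and Gfi1b (-0.21). Calls ended without any 1 of the arrays for Gfi1b (adjusted p 0.056 to 0.119), without replicates 1 or 3 of either group for Stambpl1 (up to 0.0701) and without replicate 3 of either group for Ifit3b (up to 0.0643). The Gfi1b call also ended with a variance trend on all arrays.

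The highest count of rises in a window was 6, reached at 2 places (permutation p = 0.0022). At the first, Cdkn1c (0.23) and Slc22a18 (0.29), both imprinted genes, lay near Tnfrsf26 (1.39), Tnfrsf22 (0.82), Tnfrsf23 (0.85) and Mrgpre (1.28). Calls ended without any 1 of the arrays for Cdkn1c (adjusted p up to 0.103) and without WT replicates 2 or 3 or GPS2KO replicate 3 for Slc22a18 (up to 0.0714). The Cdkn1c call also ended with a variance trend on all arrays. At the second, Tlr8 (0.78) and Tlr7 (0.53) lay beside Prps2 (0.44), Msl3 (0.36), Arhgap6 (0.68) and Hccs (0.46), which serve nucleotide synthesis, chromatin, cell shape and cytochrome assembly. The adjusted p-values of these 4 ran from 0.000258 for Arhgap6 to 0.00316 for Msl3. No explanation was tested for these runs or for the runs of falls. Segments of another strain carried along with the knockout and local regulation both stay open. That holds for Tnfrsf26, Mrgpre, Tlr8, Tlr7, Gbgt1, the class II chains and the Ifit genes as well.

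Gene families by symbol stem were compared with 17645 genes, 1224 of them past the threshold, by Fisher's exact test over 314 families with Benjamini-Hochberg adjustment. Cell surface antigens named Cd (93 tested, 15 rose, 12 fell, adjusted p = 2.77e-08), Toll-like receptors (12 tested, 4 rose, 2 fell, 0.0111), Ccl chemokines (19 tested, 6 rose, 1 fell, 0.0166), matrix metalloproteinases (20 tested, 4 rose, 3 fell, 0.0166) and Tnfrsf receptors (20 tested, 5 rose, 2 fell, 0.0166) held more called genes than the rest. Dim genes were part of the 17645, and 68 of all 1265 called genes were dim. Families expressed in macrophages could therefore hold more called genes by their brightness alone. Fisher's test also counts neighbours as independent, yet Tnfrsf26, Tnfrsf22 and Tnfrsf23 lie in 1 run, as do Tlr8 and Tlr7. Among the metalloproteinases, the macrophage elastase Mmp12 rose 2.16-fold (adjusted p = 0.000149), Mmp13 1.72-fold (adjusted p = 0.00714) and Mmp19 1.62-fold (adjusted p = 0.000479). Cxcl chemokines had 5 falls and 0 rises among 13 (adjusted p = 0.067).

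Lyz1 rose by 2.71 while Lyz2 did not change past the threshold. Granulocytes in the GPS2KO cultures are argued against as the whole source: against the 1.36 that the test asked for, the median of their markers was 0.0524 (SD 0.266 over 21 genes, 13 of them dim), that of the 8 others was 0.255 (SD 0.355), and S100a8 and S100a9 were at 0.06 and -0.07. A small share of such cells stays open, since Mmp8, Padi4 and Ngp rose and the list passed upward in 5 settings, among them without dim genes (adjusted p = 0.0132). Signal shared between the paralogs stays open, since Lyz2 (-0.0435) has only 5 tested genes above it and a rise there might not register, and so does a linked allele at the lysozyme locus: 0 of 19 neighbouring genes passed, the largest change being 0.146, but an allele acting on Lyz1 alone would leave them as they are. The genotype itself stays open as an untested explanation, and whether a Cre driver sits at Lyz2 is not in the labels.

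The fall of interferon-stimulated genes does not come from 1 array alone, since with any array left out at least 17 members fell, against 25 with all arrays. Variation between cultures that moves the genes together cannot be told apart from the genotype with 3 arrays per group: the adjusted p with an estimated correlation was 0.141, although the lowest WT mean of the list (8.27) lay above the highest GPS2KO mean (7.96).

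Gps2 kept 59.7% of its WT signal. An array labelled GPS2KO that held only wild-type RNA would lie among the WT arrays. None did: the gap between the groups was 0.642, with a larger group SD of 0.0666. A share of wild-type RNA in each GPS2KO sample would leave such a gap and stays open. A lower signal of the whole region is argued against by the median of the 40 neighbours, -0.0214 (SD 0.138). Transcript outside the deleted part and cells without the deletion cannot be told apart, because the labels do not give the deleted exons, and either could leave 59.7% of the signal.

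The 10 ways to split the 6 arrays into equal groups are too few for a share under 0.05. The real split gave 1265 genes and the highest of the others 0, and 10 lists against 3, so 1 of 10 splits reached each real count. The other splits mix WT and GPS2KO arrays within each group. Where the genotypes differ, this widens the spread within groups and lowers the count of genes, so their 0 says little about chance. With 0 genes called, camera at its preset correlation still called up to 3 lists in them.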
